A study of Mus musculus with 2 samples.

How the data were processed

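Tumour tissue grown in C57BL/6 mice was profiled by droplet single-cell RNA sequencing in 2 libraries, 1 from MC38 cells overexpressing RSPO3 and 1 from MC38 control cells. Groups were taken from the genotype in the labels. The sources used here call the tissue a xenograft, although MC38 cells and the host are both mouse. The number of mice behind each library, the tumour site and the time of harvest are not given in the sources used here.

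The deposited matrices hold raw UMI counts per gene and cell barcode, and the authors made them with Cell Ranger 3.0.1 on mm10, per the labels' protocols and the submitters' processing notes, while the matrix header gives software version 3.1.0. The labels state a target of about 6000 cells and a doublet rate under 5%. The barcodes were already called as cells when deposited, 7314 for RSPO3-OE and 7301 for Ctrl. Barcode and gene lists were used to label the matrices. They name 32285 genes by Ensembl identifier and symbol, and where a symbol occurs more than once it was given to the identifier with the most UMIs.

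Barcodes with under 200 genes or over 20% mitochondrial UMIs were left out, 150 in RSPO3-OE and 311 in Ctrl. Scrublet, from scanpy 1.11.5 with an expected rate of 0.05, marked 173 barcodes (2.41%) in RSPO3-OE and 94 (1.34%) in Ctrl as doublets, which were also left out. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen, 30 principal components and 15 neighbours were used, and both libraries were clustered together with Leiden (leidenalg 0.10.2) at resolution 1.0 without batch integration, because library and group are the same. T and NK cells, and myeloid cells, were clustered again. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 were used.

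Filters, markers, 38 gene lists, the rule for naming genes and 10 alternatives were set before the data were examined. Other choices were made after clusters and values had been seen. A cluster took the name of the class with the highest mean fold among its top markers, given at least 3 markers of at least 50 CPM and 2-fold over other cells, and stayed unnamed where markers of another class led it. This rule, and a stricter one for the second clustering that was revised more than once, were settled after the clusters had been seen. The Y-negative class, clusters under 10 CPM of 4 Y-linked genes together and under 50 CPM of Ptprc, was also defined then. It stands in place of the tumour class planned, since most tumour markers were near 0. Y-linked genes and Rspo3 argue against host cells as the source of the class as a whole. Its cells were not matched directly to the MC38 line. Whether that line lacks a Y chromosome is not given in the sources used here. The lists described, 27 of the 38, were chosen after all medians had been computed. They include lists with no shift. Cholesterol synthesis genes, planned for tumour cells, are given for macrophages, and inflammatory fibroblast genes, planned for fibroblasts, for Y-negative cells. The chromosome comparison and its settings also followed a first look at the data.

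UMIs were summed per library and class and divided by the class total to give CPM. Classes with at least 100 cells in each library were compared, which left 3. Log2 ratios are RSPO3-OE over Ctrl with exact binomial counting intervals, shares have exact Clopper-Pearson intervals, and single UMI sums exact Poisson intervals, all at 95%. A sum of 0 was replaced by a floor of 3 counts, which gives an approximate bound. With 1 library per group no test was made and no p-value was computed. A list's value is the median over members with at least 10 UMIs, with its percentile among 10000 random lists of equal size matched on mean CPM in 20 bins. The text names, per class, the 10 genes with the highest and the 10 with the lowest ratio among genes with at least 100 UMIs and 100 CPM in the higher library and at least 0.5 times their CPM over all kept cells there. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and unnamed-model genes were excluded. It also names up to 2 members with the highest and 2 with the lowest ratio per list. Some members that this rule selects are not reported here. Further list members named as examples were chosen after their values were seen. A list member under that limit of 0.5 in both libraries is described as not above the free RNA limit. The macrophage gene C1qa stood in Y-negative cells at 0.199% of its macrophage level in RSPO3-OE and 0.169% in Ctrl.

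The steps were tested on simulated counts with 200 genes changed by known folds. In the simulated Y-negative comparison of 15429 genes, 50 genes set to a log2 ratio of 1.0 came back with a median of 0.97 and 50 set to -1.0 with -1.02. In the T cell comparison of 10028 genes these medians were 0.998 and -0.99. For unchanged Y-negative genes the counting intervals covered the true value for 95.8%. They left out 0 for 10.05%, since the changed genes shift the CPM of all others, to a median of -0.02. They covered the set value for 88% of 50 macrophage genes at a log2 ratio of 2 and for 100% at -1.0. The simulated counts held counting error only, so this does not show how far the intervals cover other variation. The alternatives were cells with at least 500 genes, at most 10% mitochondrial UMIs, doublets kept, resolutions 0.5 and 2.0, separate clustering, median-of-ratios scaling, the mean of the cells' own CPM, cells thinned to 2000 UMIs, and list members with at least 50 UMIs. Another 3, list members above the free RNA limit, Y-negative cells without clusters led by fibroblast markers and sub-clusters named by their markers alone, were added after the data had been seen.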

Results

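Single-cell transcriptomes were measured in tumours grown in C57BL/6 mice from MC38 cells, a mouse colon carcinoma line. One tumour sample came from MC38 cells that overexpress RSPO3 (RSPO3-OE), a secreted R-spondin that strengthens Wnt signalling through the receptors LGR4, LGR5 and LGR6 and the ubiquitin ligases RNF43 and ZNRF3. The other came from control MC38 cells (Ctrl). Each group had 1 library, so no difference below has a replicate check, cells are not replicates, and the intervals given are 95% intervals that cover counting error only. The RSPO3-OE library held 7314 barcodes with 155615189 UMIs and the Ctrl library 7301 barcodes with 143881763 UMIs. After filtering, 6991 RSPO3-OE cells with a median of 18911 UMIs and 6896 Ctrl cells with a median of 16627 UMIs were kept. Cell class names below stand for clusters that resemble those cells by markers fixed in advance. The naming rules and the Y-negative class were set after the clusters had been seen.

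The first question is whether the overexpressed gene was read in the library labelled for it, and in which cells. Rspo3 was abundant in the RSPO3-OE library and nearly absent from the control. Rspo3 (ENSMUSG00000019880) lies on chromosome 10 from 29452416 to 29535867 on the minus strand in mm10, by the GENCODE vM21 annotation. The main carriers were cells with almost no RNA of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and almost no Ptprc, the pan-leukocyte gene, here called Y-negative cells. In these cells Rspo3 gave 14080 UMIs, or 109.4 CPM (UMIs scaled to the same total for every class; 107.6 to 111.3), in the RSPO3-OE library. The Ctrl Y-negative cells gave 0 UMIs. With the floor of 3 counts, 0.025 CPM, the log2 ratio was at least about 12.11. The exact upper limit in Ctrl was 0.030 CPM and the exact lower limit of the log2 ratio 11.81. Of the 4878 RSPO3-OE Y-negative cells, 1035 held an Rspo3 UMI, a share of 21.2% (20.1 to 22.4, exact Clopper-Pearson interval). With each cell thinned to 2000 UMIs, which left out 16 shallower cells, the share was 8.68%. Background was low: 13 of 1461 RSPO3-OE macrophages held an Rspo3 UMI, a share of 0.890% (0.475 to 1.52), at a median of 10793 UMIs per cell against 24008 in the Y-negative cells. The transcript was uneven between cells, since 381 cells with at least 10 UMIs held 84.8% of the UMIs and 247 positive cells held 1 UMI. The Ctrl library held 2 Rspo3 UMIs among all its barcodes.

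Of the R-spondin receptors, Lgr4 and Znrf3 were the ones read above 1 CPM in Y-negative cells. Lgr4 stood at 5.88 CPM (5.47 to 6.32) in RSPO3-OE and 4.52 CPM (4.15 to 4.92) in Ctrl. Znrf3 stood at 6.35 CPM (5.92 to 6.80) in RSPO3-OE and 6.84 CPM (6.38 to 7.32) in Ctrl. Lgr6 stood at 0.443 against 0.593 CPM and Rnf43 at 0.466 against 0.808 CPM. Lgr5 had 0 UMIs in RSPO3-OE, with an exact upper limit of 0.029 CPM, and 3 UMIs in Ctrl. Macrophages held 3.21 against 3.18 CPM of Znrf3 and under 1 CPM of Lgr4.

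The second question is what the tumours were made of. Immune cells took a larger share of the RSPO3-OE library, with larger shares of T cells and neutrophils. The named immune classes together made up 29.0% of kept cells (28.0 to 30.1) in RSPO3-OE and 21.9% (20.9 to 22.9) in Ctrl. T cells, marked by Cd3d, Cd3g and Trbc2, made up 5.58% (5.05 to 6.14) against 2.55% (2.19 to 2.95). Neutrophils, marked by S100a8, S100a9 and Retnlg, made up 1.46% (1.19 to 1.77) against 0.305% (0.189 to 0.465). Monocytes and macrophages made up 20.9% (19.95 to 21.87) against 18.4% (17.5 to 19.4), and NK cells or innate lymphoid cells 0.787% (0.593 to 1.02) against 0.508% (0.354 to 0.705). Dendritic cells numbered 21 and 6, at 0.3004% (0.186 to 0.459) and 0.087% (0.032 to 0.189) with overlapping intervals, and fibroblasts 19 and 13. Y-negative cells made up the remaining majority, 69.8% (68.7 to 70.9) of RSPO3-OE and 77.5% (76.5 to 78.5) of Ctrl cells. With each library clustered on its own, the T cell share was 4.71% against 3.19% and the neutrophil share 1.46% against 1.06%. The size of both differences thus depends on the clustering. The NK class changed with the T cell class: separate clustering put the NK share of RSPO3-OE at 1.69% and named no Ctrl cluster NK cells. In the main clustering the T cell and NK or innate lymphoid classes together held 445 of 6991 and 211 of 6896 kept cells. The neutrophil shares were 0.937% and 0.131% with at least 500 genes per cell. A mixed cluster led by mast cell and immunoglobulin genes stayed unnamed, with 65 and 28 cells.

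**Figure D1:**
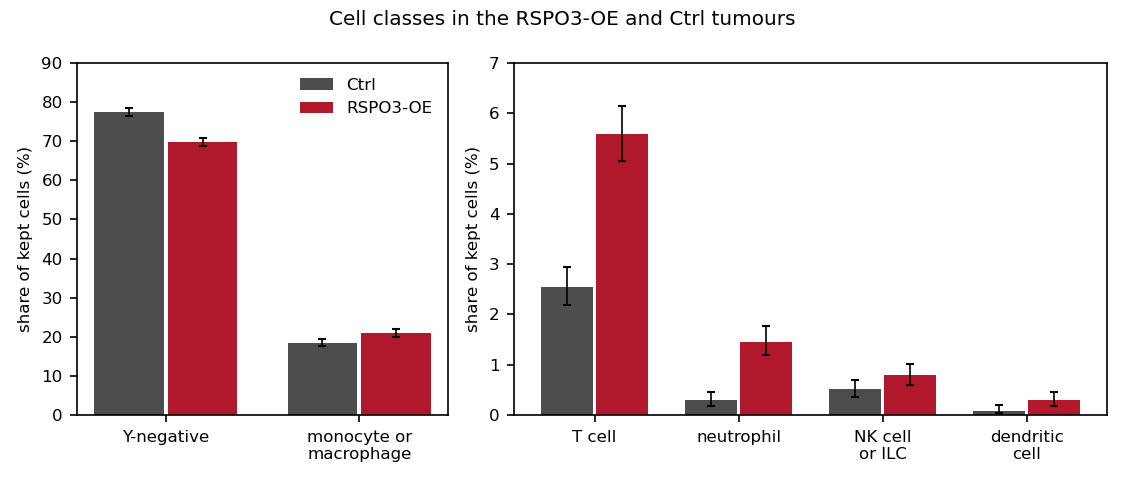
Share of kept cells in each marker-named class, in percent, in the Ctrl (grey) and RSPO3-OE (red) library, with exact 95% binomial intervals for 1 library per group. T cells were at 5.58% in RSPO3-OE and 2.55% in Ctrl, and neutrophils at 1.46% and 0.305%.

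Within the myeloid cells, monocytes with Ly6c2, Ccr2, Chil3 and Plac8 were more frequent in RSPO3-OE. They made up 22.6% of 1584 myeloid cells (20.6 to 24.7) in RSPO3-OE and 7.16% of 1299 (5.82 to 8.70) in Ctrl. Cells named macrophages by C1qa, Apoe and related genes made up 65.2% (62.7 to 67.5) and 66.2% (63.6 to 68.8), but 59.04% and 34.1% at resolution 0.5 and 45.4% and 65.2% with at least 500 genes per cell, so no order is stable. In the main clustering, unnamed myeloid clusters held 4.73% and 24.7%. Many of the latter Ctrl cells sat in 1 cluster of 44 and 294 cells that was led by haemoglobin genes but carried 12 macrophage markers, and 20 cells held nearly all haemoglobin UMIs of the Ctrl macrophages. With sub-clusters named by their markers alone, a choice made after the data had been seen, macrophages made up 69.9% of RSPO3-OE and 90.9% of Ctrl myeloid cells. Several macrophage sub-clusters came almost wholly from 1 library. One led by Retnla, Igf1, Ccl8 and Mrc1 held 344 RSPO3-OE and 11 Ctrl cells, one led by Cxcl9 and Serpina3g held 270 and 26, and one led by Nt5e, Folr2, Spp1 and Cxcl14 held 40 and 358. Whether such clusters stand for a cell type or for another difference between the libraries was not tested.

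Within the lymphoid cells, those named regulatory T cells made up 11.01% of 445 cells (8.26 to 14.3) in RSPO3-OE and 5.21% of 211 (2.63 to 9.14) in Ctrl. The intervals overlap, and the shares were 21.8% and 12.8% at resolution 0.5. Their cluster carried 7 regulatory markers, but Csf2, Ccl1, Cd4, Penk and Il17a ranked ahead of Foxp3 among its leading genes. No conventional CD4 cluster was named, so it may hold other CD4 T cells as well. CD8 T cells made up 53.9% (49.2 to 58.6) and 72.04% (65.5 to 78.0), and NK cells 9.66% and 9.95%. The CD8 order turned when cells above 10% mitochondrial UMIs were left out, at 61.5% in RSPO3-OE and 34.9% in Ctrl, where 57.0% of the Ctrl lymphoid cells lay in unnamed clusters. Unnamed lymphoid clusters held 25.4% and 12.8%, 1 led by Gzmg, Gzmf, Gzme and Gzmd with 62 and 9 cells and 1 led by myeloid genes such as Cxcl2 and Il1b with 51 and 18. Both carried 7 CD8 markers, and with the same naming by markers alone the CD8 shares were 79.3% and 84.8%, so much of the gap comes from the naming rule. A CD8 cluster led by the heat shock genes Hspa1b and Hspa1a held 10 and 93 cells.

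The third question is what the Y-negative cells expressed. Interferon gamma response genes, chemokines, matrix genes and immediate early genes were higher in RSPO3-OE, and S phase and mitochondrial transcripts were lower. After Rspo3, the genes with the highest ratios were Mgp, a matrix protein that limits calcification, at log2 2.77 (2.74 to 2.80), the keratin Krt8 at 2.57, the monocyte chemokine Ccl7 at 2.51, S100a16 at 2.37 and the nuclear receptor Nr4a2 at 2.24. The LIM proteins Crip1 and Crip2 followed at 2.17 and 2.14, the interferon-induced GTPase Iigp1 at 2.05 and the gelatinase Mmp2 at 2.03. Krt8 stood at 520.2 CPM in RSPO3-OE and 87.5 CPM in Ctrl, and Crip1 at 2443 and 544.3 CPM. The lowest ratios belonged to Rgs16, a regulator of G protein signalling, at -1.77 (-1.82 to -1.72), the histone genes Hist1h1e at -1.596, Hist1h2ap at -1.53, Hist1h1b at -1.13 and Hist1h2ae at -1.07, the transcription factor Sox4 at -1.20, the endothelial-type proteoglycan gene Esm1 at -0.98, Ccni at -0.92, AI506816 at -0.89 and the glycosyltransferase Ogt at -0.88. Reads of the near-identical histone genes can be split between copies, so single histone values are uncertain.

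Different clusters held most of this class in each library. Of RSPO3-OE Y-negative cells, 79.4% (78.3 to 80.6) lay in clusters 2, 4, 6 and 20, which held 1.31% (1.02 to 1.65) of Ctrl Y-negative cells. The other cells lay in clusters 1, 3, 5, 7, 8 and 12. Mgp was among the leading genes of clusters 6 and 20. RSPO3-OE cells outside clusters 2, 4, 6 and 20 held 34.1 CPM of Mgp, against 80.3 CPM in all Ctrl Y-negative cells. Mmp2 stood at 33.6 against 33.5 CPM in this comparison. Nr4a2, Crip1 and Crip2 were higher by much less than in the class, with Crip1 at 811.96 against 544.3 CPM. Krt8, Ccl7, S100a16 and Iigp1 stayed well above Ctrl, with Krt8 at 471.95 against 87.5 CPM. Mgp, Krt8, S100a16, Crip1 and Crip2 are among the leading genes of clusters 2, 4, 6 and 20, so this comparison is partly fixed by the clustering. The libraries were clustered together without integration. A different mix of cells therefore cannot be told apart from a shift shared by all cells of a library. Clusters 3, 6 and 20 had fibroblast markers such as Lum, Pdgfra or Col3a1 among their leading genes. They held 23.1% of RSPO3-OE and 26.4% of Ctrl Y-negative cells. The class as a whole expressed Krt8, Hmga2 and Hmga1, at 310.2, 285.6 and 131.9 CPM, but almost no Krt18 or Epcam. Y-linked genes summed to 0.373 CPM in RSPO3-OE and 0.305 CPM in Ctrl Y-negative cells, against 149.4 and 140.7 CPM in the fibroblast class. Every other class, the unnamed cluster included, held 63.0 to 376 CPM of these genes. Of 14157 Rspo3 UMIs in kept RSPO3-OE cells, 14080 lay in Y-negative cells. These values argue against host cells as the source of the class as a whole, in Ctrl by the Y-linked genes alone. That leaves the injected MC38 line, which was not profiled on its own, so a direct match was not made.

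Interferon gamma response genes were higher in RSPO3-OE almost throughout. The median log2 ratio of 19 measured members was 1.10 (1.06 to 1.14), at the 100th percentile of 10000 matched random lists, and 15 members were at least 1.5-fold higher. Iigp1 stood at 2.05, the T cell chemokine Cxcl9 at 1.90, the guanylate-binding protein Gbp2 at 1.78 and Irf1 at 1.38, while Wars stood at -0.02. The median of 18 type I interferon genes was 0.59 (0.56 to 0.62), with Rsad2 at 1.35 and Isg15 at 1.02, but Oas2 at -0.40 and Ifit2 at -0.17. It was 0.19 in cells thinned to 2000 UMIs and 0.16 with the mean of the cells' own CPM, which put Rsad2 at 0.88 and Isg15 at 0.53. The Y-negative cluster led by Rsad2, Ifit1 and Ifit3 held 90 RSPO3-OE and 711 Ctrl cells, the opposite order. At resolution 2.0 the cluster led by Rsad2, Ifit1 and Ifit3b held 45 and 12 cells. There a cluster led by Cxcl10, Gm42418 and Lars2 held 34 and 616 cells, and one led by Ogn and Fmo2 held 16 and 563. Both of these had Ifit1 and Ifit3 further down their leading genes, so the order of such clusters is not stable. All 14 MHC class I presentation genes lay above 0, with a median of 0.39 (0.39 to 0.41), from Nlrc5, the transactivator of these genes, at 1.01, or 0.66 with the cells' own CPM, down to Tap2 at 0.20. MHC class II genes had a median of 1.13, or 0.69 with the cells' own CPM and 0.72 in thinned cells, but 0 of 8 members reached 0.5 times their level over all cells. Cd74 stood at 0.334% of its macrophage level in RSPO3-OE and 0.199% in Ctrl, against 0.199% and 0.169% for the macrophage gene C1qa, so how much of this is free RNA was not settled.

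Inflammatory and stromal-type genes were also higher. The TNF and NF-kB list had a median of 0.55 (0.38 to 0.93), or 0.32 for the 13 members above the free RNA limit, with Il6 at 1.72, the NF-kB inhibitor Tnfaip3 at 1.52 and the monocyte chemokine Ccl2 at 1.49, against Csf1 at -0.37. Il6 stood at 0.86 without the clusters led by fibroblast markers. The list of myeloid chemokines had a median of 1.07, which was 0.74 for the 8 members above the free RNA limit, and its lowest member was Cxcl5 at -3.14. In thinned cells that median was 0.68 and Cxcl5 stood at -1.75. Genes of inflammatory fibroblasts, a list planned for fibroblasts, had a median of 1.47 (1.45 to 1.48), led by the hyaluronan synthase Has1 at 4.94, with Pdgfra at -0.68. Matrix genes had a median of 0.48 (0.34 to 0.52), with Col3a1 at 1.13 and Fn1 at 0.90 and Col6a1 at -0.11. TGF-beta response genes had a median of 0.66, which was 0.47 above the free RNA limit, with Ccn2 at 2.15 and Tgfbi at -0.59. Separate clustering of the libraries lowered these medians to 0.89 for inflammatory fibroblast genes, which stood at 0.96 without the clusters led by fibroblast markers, and 0.25 for both matrix and TGF-beta genes, with Ccn2 at 0.66. Checkpoint ligands had a median of 0.80, which was 0.63 for 6 members above that limit, with Pvr at 0.85 and Cd276 at -0.26, and the median was 0.42 in thinned cells. Genes of apoptosis and the p53 response had a median of 0.41, or 0.26 in thinned cells, led by the cell cycle inhibitor Cdkn1a at 1.67 and with Bax at -0.18.

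Wnt feedback genes showed no common direction. The median of 11 measured receptors and feedback genes was 0.02 (-0.08 to 0.20), at the 82.9th percentile, with Tcf7 at 1.01 and Axin2 at 0.41 but Lef1 at -1.46 and Rnf43 at -0.79. It was -0.10 with separate clustering and -0.17 with the cells' own CPM. The wider list of Wnt targets had a median of 0.28 (0.14 to 0.28), at the 99.9th percentile, with Cd44 at 0.65, Plaur at 0.63 and Myc at 0.61 but Met at -0.72 and Sox4 at -1.20. S phase genes were lower, with a median of -0.28 (-0.31 to -0.26), from Clspn at 0.18 to Dtl at -1.17. G2 and M phase genes had a median of -0.04, which turned to 0.05 with median-of-ratios scaling. Hypoxia and glycolysis genes had a median of -0.26 (-0.28 to -0.24), or -0.17 with median-of-ratios scaling, but 0 of 24 members were at least 1.5-fold lower and 2 were higher, with the cytokine Mif and the enzyme Pgam1 at -0.53 and Ndrg1 at 0.91.

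Sample quality moved with these groups. Immediate early genes, which respond to tissue handling, had a median of 1.06 in Y-negative cells, with Zfp36 at 1.37 and Junb at 1.36, and took 1.59% of UMIs in RSPO3-OE and 0.967% in Ctrl. Heat shock genes had a median of -0.46, with Hspa1b at -3.03, and the 10 mitochondrial transcripts one of -0.51. Hspa1a and Hspa1b are near-identical, so their reads can be split between them. The median of all genes in these cells was -0.09.

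**Figure D2:**
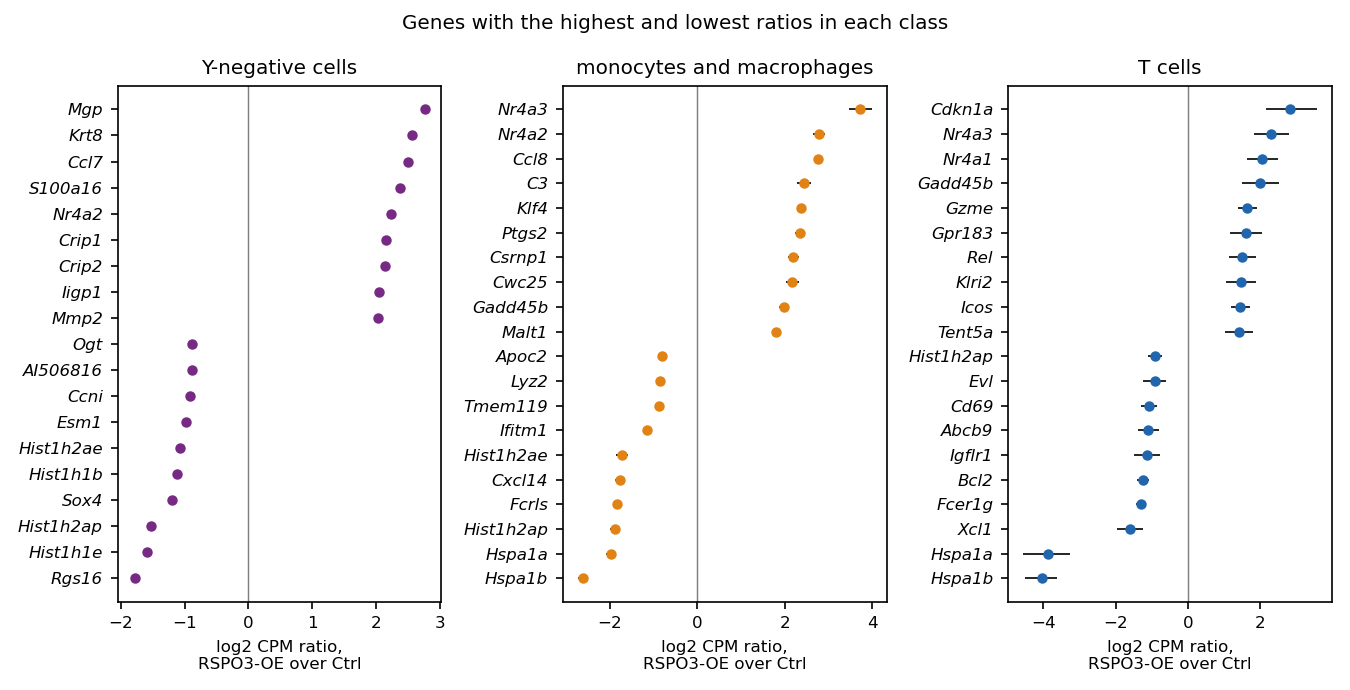
Log2 ratios of CPM, RSPO3-OE over Ctrl, for the genes with the highest and lowest ratios in each class by the fixed size rule, with exact 95% counting intervals as black lines and Rspo3 left out. Mgp at 2.77 led in Y-negative cells, Nr4a3 at 3.74 in monocytes and macrophages, and Cdkn1a at 2.83 in T cells.

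The fourth question is what the monocytes and macrophages expressed. Inflammatory genes and genes of alternative activation were both higher in RSPO3-OE, as were interferon gamma response, MHC class II and cholesterol synthesis genes, while cell division genes were lower. The highest ratios belonged to the nuclear receptors Nr4a3 at 3.74 and Nr4a2 at 2.78, the chemokine Ccl8 at 2.76, complement C3 at 2.45, the transcription factor Klf4 at 2.37, the prostaglandin synthase Ptgs2 at 2.35, Csrnp1 at 2.20, Cwc25 at 2.18, Gadd45b at 1.98 and the NF-kB activator Malt1 at 1.81. The lowest belonged to Hspa1b at -2.62 (-2.74 to -2.50) and Hspa1a at -1.98, Hist1h2ap at -1.88, Fcrls at -1.83, the chemokine Cxcl14 at -1.77, Hist1h2ae at -1.72, Ifitm1 at -1.14, Tmem119 at -0.87, the lysozyme Lyz2 at -0.85 and the apolipoprotein Apoc2 at -0.79. Ccl8 stood at 1020 CPM in RSPO3-OE and 150.4 CPM in Ctrl. Cluster 0 held the most macrophages of both libraries, 848 and 909 cells. Cluster 10, led by the monocyte genes Ly6c2, Chil3 and Ccr2, held 378 and 110. The ratios of the class therefore include this change in the mix of cells, and Chil3 and Ccl24 are leading genes of a monocyte sub-cluster and Retnla of a macrophage sub-cluster found mostly in RSPO3-OE.

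Of the 14 inflammatory macrophage genes, 13 were at least 1.5-fold higher, with a median of 1.26 (1.11 to 1.34) at the 100th percentile of matched lists. With cells matched on their share of immediate early UMIs the median was 0.82. The interleukins Il12b and Il6 stood at 4.09 and 2.69, Il1b at 1.43, Tnf at 1.10 and Nos2 at 0.96, and the costimulator Cd86 at 0.26. Of 12 alternatively activated macrophage genes, 8 were at least 1.5-fold higher and 2 lower, with a median of 1.25 (1.13 to 1.32). The chemokine Ccl24 stood at 2.88, Egr2 at 2.65, Chil3 at 2.09, Retnla at 2.08 and the anti-inflammatory cytokine Il10 at 1.84, whereas Folr2 stood at -0.90 and the scavenger receptor Stab1 at -0.66. With cells thinned to 2000 UMIs that median was 0.77 and Retnla stood at 0.45. The TNF and NF-kB list had a median of 1.0002 (0.87 to 1.19), or 0.67 with cells matched on immediate early share.

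Interferon gamma response genes had a median of 0.68 (0.64 to 0.73), and 15 of 18 were at least 1.5-fold higher, with Socs1 at 1.40 and Wars at 0.14. Type I interferon genes had a median of 0.34, with Isg15 at 0.86 and Bst2 at -0.24, while the macrophage sub-cluster led by Ifit3, Cmpk2 and Rsad2 held 33 RSPO3-OE and 93 Ctrl cells. MHC class II genes had a median of 0.53 (0.50 to 0.61), from H2-Aa at 0.78 to the protease Ctss at 0.06, which turned to -0.0102 with doublets kept, and MHC class I genes one of 0.35. Cholesterol synthesis genes, a list planned for tumour cells, had a median of 0.70 (0.63 to 0.83), led by Cyp51 at 1.55. Complement and lipid genes had a median of -0.08, with Gpnmb at 1.94 and Fabp5 at 1.33 but Apoe at -0.45 and C1qb at -0.32. With doublets kept Gpnmb stood at 0.97. G2 and M phase genes had a median of -0.65 (-0.71 to -0.56), with 13 of 20 at least 1.5-fold lower, and S phase genes one of -0.23, or -0.14 with doublets kept, with Tyms at -0.90. Of the receptor and Wnt feedback genes 4 were measured, with a median of 0.25 (-0.06 to 0.94), or 1.28 with doublets kept. Immediate early genes had a median of 0.69 and heat shock genes one of -0.33 in these cells. Haemoglobin gave 0.029% of UMIs in Ctrl macrophages, nearly all of it in 20 cells.

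The fifth question is what the T cells expressed. Genes of the regulatory T cell list were mostly higher in RSPO3-OE, cytotoxicity genes went in both directions and exhaustion genes had no common direction. The comparison rests on 390 RSPO3-OE and 176 Ctrl cells, mostly in cluster 9 with 329 and 164 cells, and in cluster 17, led by Tnfrsf4, Ctla4 and Ikzf2, with 61 and 12. Cluster 17 thus made up more of the RSPO3-OE than of the Ctrl T cells, so the median of the regulatory list also carries that share. The highest ratios belonged to Cdkn1a at 2.83 (2.16 to 3.58), the activation-induced receptors Nr4a3 at 2.29 and Nr4a1 at 2.05, Gadd45b at 1.99, the granzyme Gzme at 1.64, the oxysterol receptor Gpr183 at 1.597, the NF-kB subunit Rel at 1.49, Klri2 at 1.47, the costimulator Icos at 1.44 and Tent5a at 1.41. The lowest belonged to Hspa1b at -4.05 (-4.51 to -3.62) and Hspa1a at -3.89, the chemokine Xcl1 at -1.6003, Fcer1g at -1.30, the survival gene Bcl2 at -1.25, Igflr1 at -1.13, Abcb9 at -1.10, Cd69 at -1.07, Evl at -0.92 and Hist1h2ap at -0.91. With each library clustered on its own, the ratio was 1.88 for Cdkn1a, 0.64 for Gadd45b, 1.05 for Gzme, 0.80 for Tent5a, -0.53 for Abcb9 and -3.28 for Xcl1. With doublets kept, it was -2.54 for Hspa1a, 1.20 for Gadd45b and -1.04 for Xcl1.

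Cytotoxicity genes had a median of 0.22 (0.11 to 0.26) over 15 members, of which 4 were at least 1.5-fold higher and 3 lower. Gzme stood at 1.64 and Gzmd at 1.37, whereas Gzmk stood at -0.76 and Tnf at -0.64, and perforin, Prf1, at 0.23. Separate clustering put the median at 0.51, Gzmd at 0.42 and Gzmk at -0.0750, and with doublets kept Tnf stood at -0.0664. Granzyme genes of this cluster share sequence, so their single values are uncertain. Exhaustion genes had a median of -0.11 (-0.16 to 0.24), with Ctla4 at 0.92, Pdcd1 at 0.46, Lag3 at 0.00 and Cd244a at -0.75. That median was 0.42 with each library clustered on its own, and Cd244a then stood at -0.41. Regulatory T cell genes had a median of 0.92 (0.60 to 1.13), with 8 of 13 at least 1.5-fold higher, among them Il2ra at 1.54, Icos at 1.44 and Tnfrsf4 at 1.08, and with Foxp3 at 0.57. With separate clustering that median was 0.42, Il2ra stood at 0.42 and Foxp3 turned to -2.92. At resolution 0.5 Foxp3 stood at -0.68, so Foxp3 has no stable direction across the settings. In both settings the T cell class held 4.71% of RSPO3-OE cells in place of 5.58%. The NK class then held 1.69% with separate clustering and 1.66% at resolution 0.5, in place of 0.787%. The turns thus compare T cell classes that are made up differently. The median of naive and memory genes, 0.93 (0.33 to 1.48) with Ccr7 at 3.03, turned to -1.34 with separate clustering, which put Ccr7 at 0.28, so it has no stable direction. S phase and G2 and M phase genes had medians of -0.01 and -0.03, and of -0.19 and 0.11 with separate clustering. Interferon gamma genes had a median of 0.20 and immediate early genes one of 0.24, and both turned negative with separate clustering, at -0.16 and -0.13. The TNF and NF-kB list holds Cxcl2 and Il1b, which lead an unnamed lymphoid cluster of 51 and 18 cells. How much RNA of myeloid cells adds to that list was not settled. TNF and NF-kB genes had a median of 0.53, which was 0.33 above the free RNA limit and 0.0798 with separate clustering. Heat shock genes had one of -0.16, or -0.44 with separate clustering, and the 5 measured receptor and Wnt feedback genes one of 0.86 (-0.42 to 1.36), which turned to -1.82 with separate clustering.

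**Figure D3:**
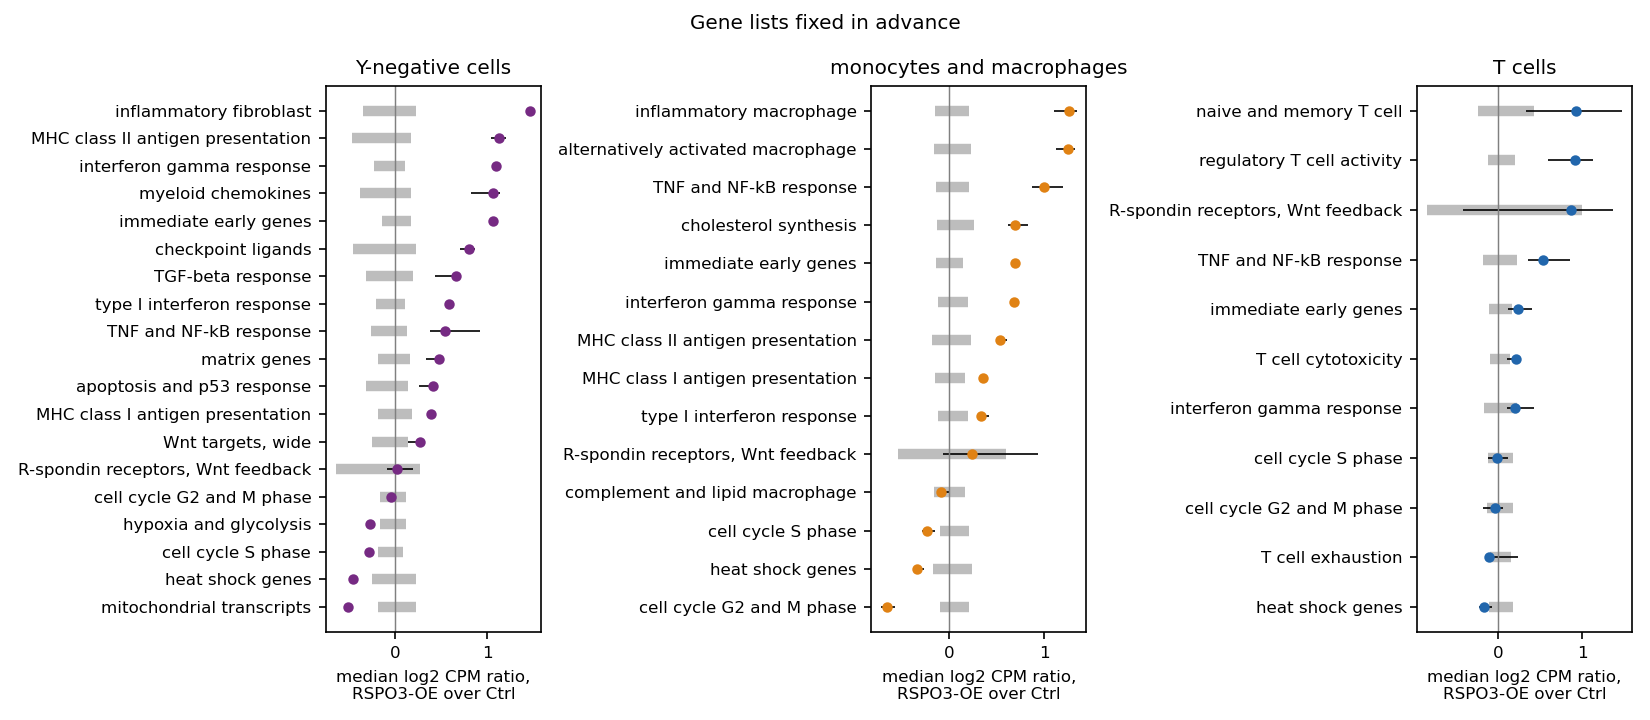
Median log2 ratio of CPM, RSPO3-OE over Ctrl, for gene lists fixed in advance, as points with 95% counting intervals in black, beside the middle 95% of 10000 matched random lists in grey. Interferon gamma response genes lay at 1.10 in Y-negative cells, 0.68 in monocytes and macrophages and 0.20 in T cells.

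The sixth question is whether the differences in Y-negative cells were spread evenly over the genome. They were not: genes of chromosome 5 were lower and genes of chromosome 15 higher in RSPO3-OE. Genes with at least 300 UMIs in both Y-negative cells and macrophages were compared. Relative to all such genes, the 473 genes of chromosome 5 had a median log2 ratio of -0.44 (-0.47 to -0.42), and 92.2% of them lay below 0. The 271 genes of chromosome 15 had a median of 0.32 (0.29 to 0.36). Chromosomes 17 and 19 stood at -0.25 and -0.19. In monocytes and macrophages of the same libraries the genes of chromosome 5 had a median of -0.016. Ccni and AI506816 lie on chromosome 5 and Krt8 lies on chromosome 15, each with a ratio in the direction of its chromosome. Other named genes went both ways. Hist1h1e, Hist1h2ap, Hist1h1b, Hist1h2ae, Sox4 and Esm1, all lower, lie on chromosome 13, whose median was 0.13. Mgp and Nr4a2, both higher, lie on chromosomes 6 and 2 with medians of -0.06 and -0.08. Rgs16, Ccl7, Crip1, Crip2 and Iigp1 went with their chromosomes.

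**Figure D4:**
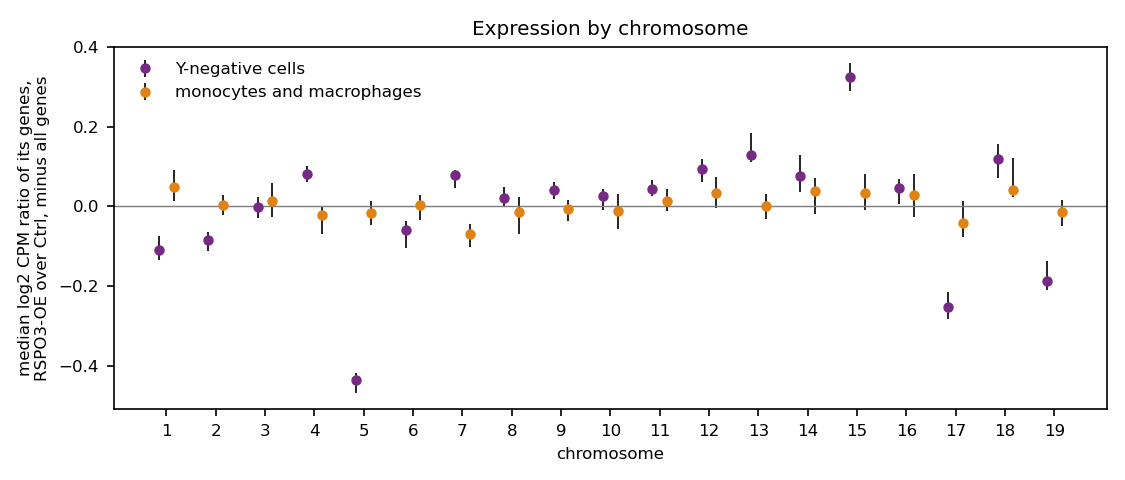
Median log2 ratio of CPM, RSPO3-OE over Ctrl, of the genes of each chromosome minus the median of all genes, with 95% intervals from redrawing genes, in Y-negative cells (purple) and monocytes and macrophages (orange). Chromosome 5 stood at -0.44 in Y-negative cells and -0.016 in monocytes and macrophages.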

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

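A value was counted as having changed direction when its sign turned and the main counting interval left out 0, and otherwise as moved when it lay outside that interval. Of 2308 gene values under the alternatives, 1835 stayed, 458 moved and 15 changed direction. Of 499 list medians, 378 stayed, 116 moved and 5 changed direction, and of 119 shares, 78 stayed and 41 moved. The values that moved or changed direction are given here for the results named first in the report and for every reversal, and the cause was not tested unless one is given. No paired analysis was possible because each group had 1 library. The alternatives were planned except the free RNA limit, the removal of clusters led by fibroblast markers and the naming of sub-clusters by their markers alone, which were chosen after seeing the data.

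Clustering each library on its own gave the most changes of direction, for 7 gene values and 3 list medians, while thinning moved the most gene values, 136 of 243. The Y-negative share of RSPO3-OE was 67.3%, the T cell shares 4.71% and 3.19%, the NK share of RSPO3-OE 1.69% and the neutrophil share of Ctrl 1.06%. No Ctrl cluster was named NK cells. The Y-negative median of Wnt feedback genes was -0.10. In T cells the medians were 0.51 for cytotoxicity, 0.42 for exhaustion and 0.42 for regulatory genes, and they turned for naive and memory genes at -1.34, interferon gamma genes at -0.16 and immediate early genes at -0.13. Single genes that turned were Lox at -0.88 in Y-negative cells and, in T cells, Cxcr6 at 0.27, Slamf6 and Ebi3 at -1.46, Iigp1 at -0.0499, and Gbp2 and Klf4 at -0.66. Of the 20 genes named for T cells, 9 were named again.

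Thinning cells to 2000 UMIs, which lowers every count, put the Rspo3 log2 ratio at 8.52 or more, since the floor in Ctrl is then higher, and the share of cells with an Rspo3 UMI at 8.68%. Interferon gamma medians were 0.93 in Y-negative cells and 0.77 in macrophages, the median of alternative activation was 0.77 and that of cytotoxicity 0.35. Naive and memory genes turned to -0.0235 and Sod2 in Y-negative cells to 0.0139. Of the genes named, 16 of 20 in Y-negative cells, 14 in macrophages and 9 in T cells were named again.

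With doublets kept, the Y-negative shares were 68.5% and 76.2%, the macrophage shares of myeloid cells 61.4% and 63.3%, and the CD8 shares of lymphoid cells 75.5% and 81.5%. The cytotoxicity median was 0.46. Ctss turned to -0.0102 and Top2a to 0.0374 in macrophages, and Gzma to 0.52 in T cells.

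With at most 10% mitochondrial UMIs, the Ctrl share was 76.0% for Y-negative cells and 19.45% for monocytes and macrophages. The CD8 shares were 61.5% and 34.9%, so their order turned, and the regulatory T cell shares were 14.8% in RSPO3-OE and 8.14% in Ctrl. The Y-negative interferon gamma median was 1.14. With at least 500 genes, which removes small cells, neutrophil shares were 0.937% and 0.131%, monocyte shares 27.4% and 9.22%, and in RSPO3-OE the macrophage share was 45.4% and the CD8 share 66.6%.

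At resolution 0.5 the RSPO3-OE shares were 4.71% for T cells and 1.66% for NK cells. Monocyte shares were 26.9% and 9.28%, macrophage shares 59.04% and 34.1%, the CD8 share of RSPO3-OE 68.5%, and regulatory T cell shares 21.8% and 12.8%. Slamf6 and Ebi3 turned to -1.10 in T cells. At resolution 2.0 monocyte shares were 27.3% and 8.84%, the macrophage share of RSPO3-OE 58.3%, and CD8 shares 42.02% and 62.6%. With sub-clusters named by their markers alone, which leaves none unnamed, macrophage shares were 69.9% and 90.9% and CD8 shares 79.3% and 84.8%.

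With the mean of the cells' own CPM, the Wnt feedback median was -0.17 and interferon gamma medians were 0.85 in Y-negative cells and 0.74 in macrophages. The inflammatory median was 1.36, that of alternative activation 1.10 and that of cytotoxicity 0.31. Median-of-ratios scaling gave 1.19 for Y-negative interferon gamma genes, and turned the G2 and M phase median to 0.0475 and Klf6 to 0.0149 in these cells. List members above the free RNA limit gave 1.18 for Y-negative interferon gamma genes. Without clusters led by fibroblast markers that median was 0.96 and Klf6 turned to 0.00756. With at least 50 UMIs per member the regulatory T cell median was 0.58.

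Of the 3 classes compared, T cells had the lowest median depth, 6753.5 and 6780.5 UMIs per cell, and depth also limits rare receptors such as Lgr5 in every class.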

Other observations

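The tests of copy number along chromosomes 5 and 15 and the test of neutrophil RNA were chosen only after the result was seen. The pattern along chromosomes was itself found by looking at the data.

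Among the named immune cells of each library, monocytes and macrophages made up 72.01% of 2029 cells in RSPO3-OE and 84.2% of 1510 in Ctrl. T cells made up 19.2% and 11.7%, and neutrophils 5.03% and 1.39%.

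Lower genes of chromosome 5 and higher genes of chromosome 15 could come from a technical difference that acts on them in every cell, and that was argued against by the macrophages of the same libraries. Their medians were -0.016 (-0.045 to 0.014) for chromosome 5 and 0.034 (-0.0078 to 0.082) for chromosome 15. Different numbers of copies in the Y-negative cells stay open. In these cells 8 of 8 windows of 20 Mb on chromosome 5 and 6 of 6 on chromosome 15 passed 0.1 in the direction of their chromosome, but this nearly follows from the chromosome medians, and 5 of 5 windows on chromosome 17 and 3 of 3 on chromosome 19 passed too, so it decides nothing. RSPO3-OE cells in clusters mostly of the Ctrl library showed the pattern too, at -0.37 for 725 genes of chromosome 5 and 0.15 for 474 of chromosome 15. These are the genes with at least 300 UMIs in Y-negative cells, a wider set than the one compared with macrophages. DNA was not analysed here.

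Inflammatory macrophage genes and immediate early genes were higher together in RSPO3-OE macrophages. With 873 cells per library matched on their share of immediate early UMIs, the inflammatory median was 0.82 (0.69 to 0.97) in place of 1.26, so a response to handling cannot be told apart from a difference between the tumours for part of it, because matching lowered the median without removing it. After matching, the TNF and NF-kB median was 0.67 and that of alternative activation 1.10, also lower, while those of interferon gamma and MHC class II genes were 0.68 and 0.56. RNA of neutrophils was argued against, since neutrophil RNA, read from S100a9, carried a median of 0.00921% of the members' differences. A difference between the tumours that RSPO3 brings about stays open and was not tested.

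Within clusters, the Rspo3 level of the same cell did not go with the genes higher in RSPO3-OE Y-negative cells. For 9 such genes, 377 cells with at least 10 Rspo3 UMIs had a median log2 ratio of -0.27 (-0.31 to -0.23) over cells with none. Between the libraries it was 2.24. The median of 18 interferon gamma genes within clusters was -0.09. The 9 genes were picked by their ratio in these data, and Mgp, Krt8, S100a16, Crip1 and Crip2 are leading genes of the clusters. Comparing within clusters can hold their variation fixed, so it cannot judge a link across clusters. A cell with no UMI may still express Rspo3. Rspo3 stood at 251.8 CPM in RSPO3-OE cells of clusters mostly of the Ctrl library and at 70.6 CPM in the others. The 9 genes were all lower in the former, with Mgp at 34.1 against 686.3 CPM and Krt8 at 471.95 against 533.4 CPM. Across clusters these genes were thus not higher where Rspo3 was, but several of them lead the clusters, so this order is partly fixed by the clustering. A secreted factor acting on neighbouring cells alike is not excluded.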
